A study of Vibrio alginolyticus with 2 samples.

How the data were processed

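The series holds single-cell RNA-seq of biofilm cells of Vibrio alginolyticus in 2 libraries, B1 and B2, of 1 group. Per the labels, cells were permeabilised, single-stranded DNA was blocked, RNA was reverse-transcribed with random primers inside the cells, adaptors were ligated to the cDNA, and droplets with barcoded beads added a cell barcode and a UMI, before paired sequencing with reads of 150 bp. A UMI therefore marks a piece of cDNA, and 1 transcript can give several. The authors aligned reads with STAR 2.7.10a and counted with STARsolo, and deposited a matrix of UMI counts per gene and cell for each library, with no normalization. The genome build, the rule for reads that map to several genes and the rule by which the authors kept barcodes are not given in the sources used here; the lowest barcode held 128 UMIs in B1 and 112 in B2. The files pair a locus tag with a symbol for 975 of 5124 features. Features were 4856 genes, 98 predicted RNAs, 40 rRNA and 130 tRNA features, told apart by the form of the tag, and the order of genes was taken from the tag number. Empty droplets were not used here, so free RNA was not estimated.

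Cells needed 50 UMIs outside rRNA and tRNA, which kept 4990 of 5010 cells in B1 and 5003 of 5021 in B2; rRNA and tRNA stayed out of depth, clustering and tests. Each UMI was put at random (share 0.5, seed 1) in a training or a held-out part. Cells were clustered on the training part: counts scaled to the median depth, log(1+x), the 1000 most variable genes among those seen in 10 cells, genes centred and scaled within each library and limited to 10, 15 principal components, 15 neighbours and Leiden clustering at resolution 0.5 with seed 0 (scanpy 1.11.5, igraph 0.11.9). The variable genes follow the rule of Seurat version 3 in scanpy, computed with a loess of span 0.3 and degree 2 in R 4.3.3, since the package scanpy uses for it was missing. A cluster needed 20 cells in each library, which all 11 had. Held-out UMIs were summed to 22 sums of cluster and library, with 11879 to 64722 UMIs each, and tested with edgeR 4.0.16: genes filtered by filterByExpr, TMM factors, cluster and library in the model, 10 residual degrees of freedom, a common dispersion of 0.0100 and quasi-likelihood tests over all clusters and of each cluster against the mean of the others. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05, and called higher or lower at a log2 fold change of at least 1 in size. Splitting UMIs does not part the UMIs of 1 transcript, so the parts are not fully independent.

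Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg over 165 pairs of list and cluster; camera with an estimated correlation and fry were alternatives. Members of a list are counted as higher or lower with no minimum of the fold change. The lists, the tests, the first set of alternatives and the rule for named genes were fixed before the data were examined. Symbols that the lists' patterns had caught wrongly, such as tRNA ligases among amino acid synthesis genes, were taken out after the symbols were seen and before any test. Named genes were the 15 with the highest CPM; in each cluster the 8 with the largest fold change among higher genes and the 4 among lower genes, with the same sign in each library alone and a mean CPM of at least 50; the 15 most variable; and up to 4 members of a list with the smallest p. Genes without a symbol were passed over. Fold changes from 1 library used a prior count of 2. For genes with 0 UMIs in a cluster a bound from 3 counts over the cluster is given, and for 1 to 3 UMIs the ratio of pooled counts with its exact (Clopper-Pearson) 95% interval; both cover counting error only.

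Variability was the variance of Pearson residuals of each gene with at least 50 UMIs in each library, set against the highest value among genes of like mean (20 bins) in 20 simulated libraries. Co-variation was the mean correlation of residuals over pairs of list members over 10 genes apart, as a percentile among 10000 random lists of like expression. For the tests of flagellar genes, each gene of the flagellum and chemotaxis list was put with flaA or flaC by its higher r in 1 library, and correlations were measured in the other; between groups they were set against the geometric mean of those within, and within the flaA group against random lists. These replaced first forms, whose groups came from clusters 5 and 7 of the same cells, after the values had been seen. Agreement of the libraries used log2 CPM with a prior count of 1.

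The steps were tested on simulated data. With changes put into 200 genes of cluster 1 by simulation, 66% of 2-fold and 92% of 4-fold changes were recovered, with 3 false calls among 161. Simulated cells with no structure gave 3 clusters and 0 of 2551 genes differing in edgeR, with 121 at an unadjusted p under 0.05. A second simulation gave each gene the median residual variance of its library (1.47 in B1 and 1.46 in B2) through several UMIs per transcript, 1.23 on average, and no other structure. It was added after the cluster results were known, and its first form used a variance entered by hand from those results, which was replaced by the value computed from the counts. It gave 13 clusters, 24 of 907 genes differing, at most 4 genes higher in 1 cluster, and 2 list calls. Each of its transcripts lay in 1 gene, so transcripts over several neighbouring genes were not simulated. DESeq2 1.42.0 was an alternative test; others were RLE factors, no count filter, all UMIs, no library term, 4 sums per cluster, another split, resolution 1.0, minimums of 100 and 10 UMIs per cell, no centring, rRNA and tRNA kept, each library alone, thinning of cells, and, added after the data were seen, no cells of over 1000 UMIs, no cluster 11, all UMIs clustered and matching of clusters by profile. Scrublet marked no cell as a doublet, so doublets were not removed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.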

Results

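Single-cell RNA-seq measured the transcripts of individual Vibrio alginolyticus cells taken from mature biofilms grown on LB agar for 60 h at 28 °C. There was 1 group, biofilm, with 2 libraries, B1 and B2. B1 held 5010 cell barcodes and 1147342 UMIs, with a median of 184 UMIs and 105 genes per cell. B2 held 5021 cell barcodes and 1012668 UMIs, with a median of 160 UMIs and 94 genes per cell. rRNA took 25.7% of the UMIs in B1 and 24.5% in B2. Without rRNA and tRNA the median depth was 138 UMIs per cell in B1 and 120 in B2. The series was collected to study how cells of a biofilm differ in function, and no second condition was sampled, so the comparisons below are between cells of these biofilms. Values with ± are the mean and SD of the 2 libraries (n = 2), and CPM is the count of UMIs scaled to the mRNA UMIs of the library, or for a cluster to its mRNA UMIs times its TMM factor, so that CPM of all genes need not add up to the same sum in each cluster. The files give a symbol for 975 of 5124 features and no product names or positions, so genes are named by symbol and the genome build is not given in the sources used here.

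Genes of the breakdown of fatty acids, of central carbon metabolism and of the ribosome were among the most abundant transcripts with a symbol; features with a symbol held 35.3% of the mRNA UMIs in B1 and 33.8% in B2. The most abundant transcript with a symbol was fadB, which encodes a subunit of the fatty acid oxidation complex, at 10444 ± 864 CPM. Behind it came sucA, a subunit of 2-oxoglutarate dehydrogenase, at 7267 ± 450 CPM, and pckA, the phosphoenolpyruvate carboxykinase of gluconeogenesis, at 7159 ± 135 CPM. The ribosomal protein gene rplT reached 5230 ± 357 CPM, and malE, the maltose-binding protein, 5063 ± 388 CPM. The fatty acid degradation genes fadE, fadJ and fadA stood at 5060 ± 506, 3808 ± 221 and 3752 ± 219 CPM. The rest of the 15 named genes with the highest CPM were rplB, gltB, atpB, argD, acsA, clpA and secY, between 3173 and 3592 CPM. A further 23 features without a symbol ranked above the 15th named gene.

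By gene list, 53 ribosomal protein genes took 6.19 ± 0.41% of the mRNA UMIs and 5 fatty acid degradation genes took 2.47 ± 0.19%. Lists hold only genes with a symbol, so a share is that of the listed genes and not of the whole function. Aerobic respiration and ATP synthase (16 genes) took 1.58 ± 0.15% and the TCA cycle (6 genes) 1.44 ± 0.025%. Amino acid synthesis (64 genes) took 1.26 ± 0.016% and glycolysis and gluconeogenesis (7 genes) 1.11 ± 0.024%. The 43 flagellum and chemotaxis genes took 0.985 ± 0.044%, translation factors 0.956 ± 0.0049% and heat shock and protein quality genes 0.855 ± 0.032%. Nucleotide synthesis took 0.803 ± 0.014%, replication and cell division 0.551 ± 0.023%, porins and outer membrane proteins 0.470 ± 0.0079% and anaerobic respiration and fermentation 0.440 ± 0.0093%. Stationary phase and stringent response took 0.425 ± 0.0027%, fatty acid synthesis 0.238 ± 0.017%, the SOS response 0.157 ± 0.00089% and quorum sensing 0.120 ± 0.0028%. Drug efflux took 0.0223 ± 0.0031% and compatible solutes 0.0143 ± 0.0035%. Across 4922 genes the log2 CPM of the 2 libraries had a Pearson r of 0.968 and a Spearman rho of 0.975, and 92.2% of the genes lay within 2-fold. These correlations are across genes, which are not independent replicates. The libraries still differed beyond counting noise. Over 4204 genes with at least 20 UMIs, the chi-square of their gene counts was 3.08 per degree of freedom, where counting noise of independent UMIs gives about 1. UMIs of 1 cell were not independent, as the median residual variance of genes over cells was 1.47 in B1 and 1.46 in B2. Part of the excess may therefore come from the draw of cells.

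To ask which functions set cells apart, the cells were grouped into 11 clusters on a random part of their UMIs, and genes were tested between clusters on the remaining UMIs. Clusters are called by number, from the largest to the smallest. Of 1463 genes tested, 732 differed between clusters, 227 of them with a symbol (edgeR, adjusted p under 0.05). Against the mean of the other clusters on the log scale, 644 genes were at least 2-fold higher in 1 cluster or more and 297 were at least 2-fold lower. Of the genes, 92 were higher in 2 or more clusters. The CPM given for the other clusters are plain means, so a fold change can exceed the ratio of the CPM beside it. The labels do not say whether the 2 libraries come from separate cultures, so p-values cannot be read as spread between cultures, and what they measure may be technical. They rest mainly on UMI counts and a dispersion shared by genes, and the spread of a single gene between the libraries entered little. The gene motB in cluster 5, at 2.77 but 1.28 in B2 alone, still had an adjusted p of 8.3e-12 (edgeR). As 1 transcript can give several UMIs, p-values may be too small. Cells were placed in clusters with little certainty: clusters made from the other part of the UMIs shared an adjusted Rand index of 0.140 with these, against 0.00064 for shuffled labels. In simulated cells with no structure other than several UMIs per transcript, 13 clusters were also found, 24 of 907 genes differed between them and 2 list calls were made. These simulated cells held no transcripts over several neighbouring genes, and every gene was given the median variance of its library. Where the log2 fold change from 1 library alone moves the fold of a called gene with over 3 UMIs in the cluster by over 1.5 times, it is given beside the gene; these values are drawn toward 0 by a prior count of 2. Settings that ended the call of a gene are given in its cluster's paragraph only for genes named there. All named genes and list members picked by the rules had 130 such cases, more than the paragraphs give. Among these settings, 4 sums are each cluster set against all other cells.

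Cluster 5 (11.1 ± 0.29% of cells) was high in genes of the flagellar filament, motor and chemotaxis. The flagellin gene flaA reached 11124 ± 1750 CPM there against 1761 ± 55 CPM in the other clusters, a log2 fold change of 2.75 (adjusted p = 3.4e-146). The filament cap gene fliDP rose by a log2 fold change of 2.51, and cheA, the chemotaxis histidine kinase, by 1.95. The motor gene motX rose by 3.53 (2.80 in B1 alone), motB by 2.77 (1.28 in B2 alone) and flaF by 2.93 (2.21 in B2 alone). The genes cheR and flaG rose by 2.68 (1.68 in B2 alone) and 2.35 (1.55 in B2 alone). Of the 22 flagellum and chemotaxis genes tested, 12 were higher, 0 were lower and 10 did not pass, with 13 higher when adjusted over the list alone. The list as a whole was higher (camera, adjusted p = 3.3e-22) and remained so with an estimated correlation (adjusted p = 0.00078). In all, 45 genes were higher and 2 lower. Cluster 5 held 8 of the 21 cells of over 1000 UMIs in B1 and 6 of the 14 in B2, and was found again without such cells.

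Cluster 7 (6.68 ± 0.54% of cells) was high in other flagellar genes. The flagellin gene flaC reached 6590 ± 92 CPM against 648 ± 135 CPM in the other clusters, a log2 fold change of 3.50 (adjusted p = 8.7e-97). The flagellar basal body and hook genes flgH1, flgI2, flgK-1 and flgL-1 rose by 3.74 (3.01 in B1 alone), 2.84, 3.67 (3.02 in B1 alone) and 3.53 (2.88 in B2 alone). The motor gene motY rose by 3.37 (2.73 in B1 and 2.22 in B2 alone), and flgJ and fliP-1 by 3.28 (2.59 in B2 alone) and 1.74 (0.91 in B1 alone); in all, 29 genes were higher and 9 lower. Of the 22 genes of the list, 9 were higher, 0 were lower and 13 did not pass, with 11 higher when adjusted over the list alone (camera, adjusted p = 5.4e-17, and 0.00115 with an estimated correlation). In this cluster flaA had a log2 fold change of -0.09 and motB of -0.85, and in cluster 5 flaC had one of -0.05, none of which passed. The propionate gene prpB, a methylisocitrate lyase, fell by 1.56 on the log2 scale. The calls of fliP-1 and prpB ended with DESeq2 and without a filter on low counts, that of fliP-1 also in the 4 sums and that of prpB with all UMIs. A direct contrast of cluster 5 with cluster 7 was not tested.

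**Figure D1:**
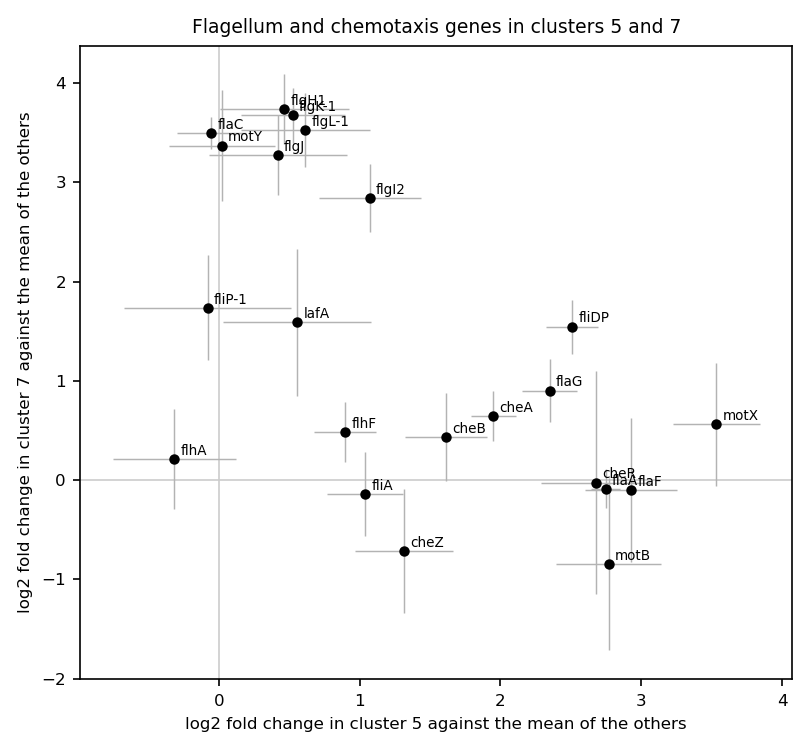
Log2 fold change of each of the 22 flagellum and chemotaxis genes in cluster 5 (horizontal axis) and cluster 7 (vertical axis) against the mean of the other clusters; bars are the standard errors of the fit. The gene flaA lies at 2.75 in cluster 5 and -0.09 in cluster 7, and flaC at -0.05 and 3.50.

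Cluster 10 (3.80 ± 0.064% of cells) was high in ribosomal protein genes. Of 52 tested, 49 were higher, 1 was lower and 2 did not pass, with 50 higher when adjusted over the list alone; their mean log2 fold change was 1.59 and their median 1.68 (camera, adjusted p = 5.6e-70, and 9.3e-05 with an estimated correlation). The gene rpsJ reached 10805 ± 1211 CPM against 2389 ± 320 CPM, rplB 12865 CPM against 3776 CPM, and rplI rose by a log2 fold change of 2.35. In all, 156 genes were higher and 98 lower; leaving out predicted RNAs, 92 of 151 higher genes lay in runs of neighbours, and the longest run, of 27 genes, started at rpsJ. Among other genes, cspA, a cold shock protein, rose by 2.94 (2.10 in B2 alone), obg, a ribosome-associated GTPase, by 2.76 (1.80 in B2 alone) and rluB, a 23S rRNA pseudouridine synthase, by 2.64. The genes emrD, rimK and secE rose by 2.53, 2.29 and 2.22, and by 0.92, 0.84 and 1.36 in B1 alone. All 5 fatty acid degradation genes were lower, with fadB at -0.83 and fadA at -0.99, but the list call (adjusted p = 0.0039) was lost with an estimated correlation (adjusted p = 0.083). Aerobic respiration and ATP synthase genes were higher, 8 of 14 (adjusted p = 0.042), with nqrE at 1.60 and nqrA at 0.88, a call also lost with an estimated correlation (adjusted p = 0.239). The rRNA share of UMIs was 13.1 ± 0.27% in cluster 10, against 24.8 ± 1.1% in cluster 1. Of the named genes that were lower, hmuV had 0 UMIs and was at least 2.22-fold lower by a floor of 3 counts over the cluster. The zinc exporter gene zntA had 3 UMIs, 7.59-fold lower with a 95% counting interval of 2.58 to 36.9; ilvD and malT had 2 UMIs each, 5.89-fold lower (1.61 to 48.9) and 4.88-fold lower (1.33 to 40.5). With DESeq2 the calls of hmuV, ilvD and malT ended; those of hmuV and malT also did with all UMIs, without a filter on low counts and in the 4 sums, and that of malT with size factors of DESeq2 and without the library term.

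Cluster 11 (2.27 ± 0.32% of cells) had a flatter profile than the others, with weakly expressed genes higher and strongly expressed genes lower. Summed over the eighth of genes with the lowest expression the log2 ratio to the other clusters was 1.84 ± 0.14, and over the eighth with the highest it was -1.28 ± 0.055; without TMM factors these were 2.40 ± 0.035 and -0.72 ± 0.055. The 3715 lower-expressed genes took 40.7 ± 2.7% of its UMIs, against 17.6 ± 0.72% in all cells. Ribosomal protein genes were lower, 29 of 52 (36 adjusted over the list alone), with rplB at -1.22, rplC at -1.62 and rpsQ at -2.34 (-1.63 in B1 and -2.96 in B2 alone); the list's adjusted p was 2.2e-14, and 0.0148 with an estimated correlation. Over 44 strongly expressed ribosomal protein genes the median log2 fold change was -1.15 in B1 and -1.30 in B2, against -0.74 and -0.85 in genes of like expression. All 5 fatty acid degradation genes were lower, with fadB at -1.14 (list adjusted p = 4.6e-05, and 0.0159 with an estimated correlation). On average they fell no further than genes of like expression: their log2 fold changes less the median of 10 such genes had a mean of 0.02 in B1 (SD 0.45 over genes) and -0.06 in B2 (SD 0.49). Single genes went both ways, from -0.38 (fadA) to 0.66 (fadE) in B1 and from -0.88 (fadJ) to 0.43 (fadE) in B2. Aerobic respiration and ATP synthase genes were lower, 5 of 14, among them atpB at -0.97 and atpA at -1.10 (-1.90 in B1 alone and -0.52 in B2 alone), a call (adjusted p = 0.016) lost with an estimated correlation (adjusted p = 0.145). Against genes of like expression, 11 genes of this list differed by a mean of -0.22 in B1 (SD 0.82 over genes) and 0.03 in B2 (SD 0.47). Weakly expressed genes rose as a whole in this cluster, and the higher genes named next were not set against genes of like expression. Named genes that were higher rested on few UMIs: mexF, an efflux pump gene, rose by 2.84 on 15 UMIs, dnaE2, an error-prone polymerase, by 3.09 on 16 UMIs (2.22 in B1 alone), uvrC, an excision repair nuclease, by 3.13 on 12 UMIs (1.99 in B2 alone) and uhpT, a hexose phosphate transporter, by 4.39 on 10 UMIs (2.84 in B1 and 2.29 in B2 alone). The genes creD, attFG, emrD and tsaD rose by 3.49, 2.91, 2.83 and 2.69, by 2.85, 2.27, 2.16 and 2.06 in B1 alone and by 2.33, 1.85, 1.49 and 1.77 in B2 alone. The genes gcvH, luxS and oppD had 1 UMI each and were 12.8-fold lower (95% counting interval 2.29 to 508.7), 8.31-fold lower (1.48 to 329.7) and 7.73-fold lower (1.37 to 306.5). DESeq2 ended the calls of these 3, the 4 sums those of luxS and oppD, size factors of DESeq2 that of oppD, and all UMIs those of emrD and tsaD. With size factors of DESeq2 the median of all genes in this cluster moved by 0.246 on the log2 scale, and 218 genes were higher and 46 lower in place of 171 and 117. The rRNA share was 15.8 ± 2.6%.

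**Figure D2:**
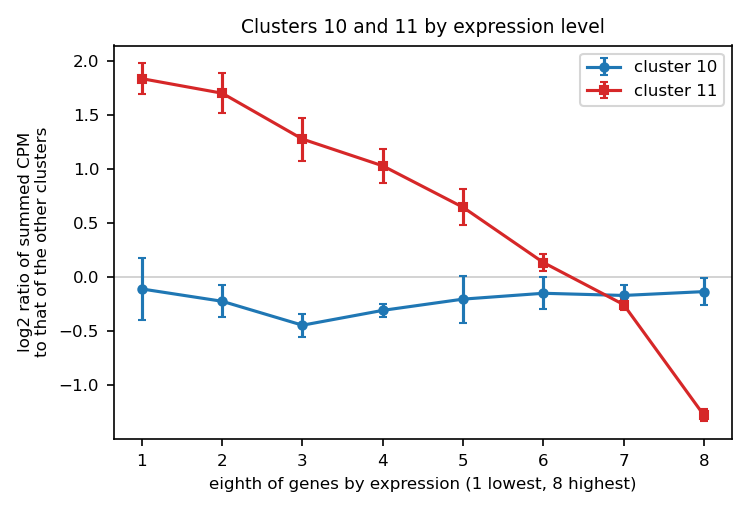
Log2 ratio of the summed CPM of genes in clusters 10 and 11 to that in the other clusters (vertical axis), by eighth of genes from the lowest to the highest expression (horizontal axis); points are means of the 2 libraries and bars SD. Cluster 11 falls from 1.84 to -1.28, while cluster 10 lies between -0.44 and -0.11. The CPM hold TMM factors; without them cluster 10 lies between -0.38 and 0.04.

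Cluster 4 (11.2 ± 0.50% of cells) was high in fatty acid degradation genes. Of the 5, 4 were higher, all 5 when adjusted over the list alone, with fadB at 19717 CPM against 11159 CPM and fadA at a log2 fold change of 1.08 (list adjusted p = 2.7e-06, and 0.0095 with an estimated correlation). The chitin-binding protein gene gbpA rose by 1.63, phhA, phenylalanine hydroxylase, by 1.61 and clpS, the adaptor of the ClpAP protease, by 1.49. The lateral flagellin gene lafA rose by 2.77 (0.92 in B1 alone) and crl by 1.94 (1.33 in B2 alone), and oadG, flgH1 and flgL-1, the last at only 0.56 in B2 alone, were also higher. By plain means, flgH1 stood at 418 CPM against 277 CPM in the other clusters and flgL-1 at 391 CPM against 272 CPM, both under 2-fold. Of the 22 flagellum and chemotaxis genes 8 were higher and 0 lower in this cluster, but the list was not called by camera (adjusted p = 0.053, and 0.342 with an estimated correlation). Ribosomal protein genes were lower, 22 of 52, with rpsJ at -1.19 and rplD at -1.33 (adjusted p = 1.8e-08, and 0.086 with an estimated correlation). Aerobic respiration and ATP synthase genes were lower, 6 of 14, with atpA at -0.60 (adjusted p = 0.010, and 0.134 with an estimated correlation). Named genes that were lower were ffh at -1.96 (-0.95 in B1 alone), yidC at -1.87 and thiI at -1.59 (-0.83 in B2 alone), and rimK with 1 UMI, 12.1-fold lower (95% counting interval 2.13 to 483.5). In the 4 sums the calls of flgH1, flgL-1, thiI and rimK ended; that of rimK also ended with DESeq2, and that of ffh with all UMIs. The rRNA share of UMIs was 32.4 ± 1.7% in this cluster.

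Cluster 2 (15.1 ± 1.6% of cells) was also high in fatty acid degradation genes: all 5 were higher, with fadB at 0.78 and fadA at 0.72 (list adjusted p = 1.1e-08, and 0.0031 with an estimated correlation). The propionate gene prpB rose by 1.44 and iscS, a cysteine desulfurase, by 1.01, and yieM was also higher. TCA cycle genes were higher, 4 of 6, with sucA at 0.51 (adjusted p = 0.036, and 0.239 with an estimated correlation). Ribosomal protein genes were higher, 5 of 52, with rplN at 0.68 (adjusted p = 0.036, and 0.445 with an estimated correlation). Flagellum and chemotaxis genes were lower, 2 of 22, flaG at -1.29 and flaA at -0.59 (adjusted p = 0.0020, and 0.134 with an estimated correlation). The glycerol phosphate transporter gene glpT was lower, at -1.16. The calls of yieM, glpT, rplN and flaA ended with DESeq2, those of glpT, flaG and flaA without a filter on low counts, and that of glpT also with all UMIs and without the library term.

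Cluster 9 (5.15 ± 0.51% of cells) was high in 3 neighbouring genes, glpK, glpT and glpQ, the only ones with a symbol among its 19 higher genes; no gene list covers them. The glycerol kinase gene glpK reached 9040 ± 1.6 CPM against 773 ± 88 CPM, a log2 fold change of 3.69 (adjusted p = 4.2e-120). The transporter gene glpT rose by 2.77 and the phosphodiesterase gene glpQ by 3.46 (1.94 in B1 and 2.81 in B2 alone). In all, 19 genes were higher and 1 was lower. Ribosomal protein genes were lower, 1 of 52, rplA at -0.97 (list adjusted p = 0.0018, and 0.272 with an estimated correlation). The calls of glpQ and rplA ended in the 4 sums. Cluster 8 (5.85 ± 0.40% of cells) was high in cysN and cysD, neighbouring genes that encode the subunits of sulfate adenylyltransferase: cysN reached 2190 ± 444 CPM against 214 ± 6.7 CPM, a log2 fold change of 3.51 (adjusted p = 2.8e-32), and cysD rose by 2.77 (1.99 in B2 alone). The amino acid synthesis list, which holds both, was not called by camera (2 of 25 higher, adjusted p = 0.455). Of its 37 higher genes, 5 had a symbol, the others being rpsP, nqrC and prpB, and the longest run of neighbours was 10 genes without a symbol. Its lower genes included gbpA, at -1.33. Flagellum and chemotaxis genes were lower in cluster 8, 1 of 22, flaA at -0.68 (adjusted p = 0.0015, and 0.128 with an estimated correlation). For rpsP, nqrC, prpB, gbpA and flaA in cluster 8 the calls ended with DESeq2 and without a filter on low counts; those of gbpA and flaA also ended without the library term, that of rpsP with all UMIs, that of prpB in the 4 sums and that of nqrC without cluster 11.

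Cluster 1 (15.3 ± 1.2% of cells) was high in glyA1, serine hydroxymethyltransferase, at 4449 ± 658 CPM against 1680 ± 111 CPM (log2 fold change 1.44, adjusted p = 3.4e-28). The cryptochrome gene cry rose by 1.66 (adjusted p = 3.4e-21) and zntA by 1.28. The gene mraY, of cell wall synthesis, rose by 1.80 (0.90 in B2 alone), and cry2, nqrB-2 and hemH rose by 1.52, 1.51 and 1.42, and hmuV was also higher; in B1 alone cry2, nqrB-2, hemH and hmuV were at 0.82, 0.49, 0.74 and 0.48, under the limit of 1. The gene fliDP was lower, at -1.09. DESeq2 ended the calls of mraY, cry2 and hmuV, the 4 sums also that of hmuV, and the fit without a filter on low counts that of fliDP. No gene list was called by camera in cluster 1. Cluster 3 (12.8 ± 0.35% of cells) was high in clpB, a protein disaggregase, by 1.34 (adjusted p = 4.4e-07), pspB, a phage shock protein, by 2.26 (1.41 in B1 and 1.64 in B2 alone), the cell division gene zapC by 1.21 and recA by 1.01. The genes leuO, glmS and zipA, of which the last is also a cell division gene, were also higher, and flaC was lower, at -1.05. In cluster 3 heat shock and protein quality genes were higher, 3 of 11 and 6 adjusted over the list alone, namely clpB, rpoH at 0.86 and groL1 at 0.82 (list adjusted p = 0.019, and 0.276 with an estimated correlation); no cluster had a call of this list with another split of the UMIs, at resolution 1.0 or with clusters made without the list. The calls of rpoH and groL1 ended with DESeq2, in the 4 sums and without the library term, that of groL1 also with size factors of DESeq2, without a filter on low counts and without cluster 11, and that of leuO with all UMIs and in the 4 sums. Lower lists in cluster 3 were fatty acid degradation, 3 of 5 (adjusted p = 0.118 with an estimated correlation), the TCA cycle, 2 of 6 (adjusted p = 0.167 with an estimated correlation), flagellum and chemotaxis, 4 of 22 (adjusted p = 0.173 with an estimated correlation), and ribosomal proteins, 0 of 52 (adjusted p = 0.374 with an estimated correlation). Cluster 6 (10.9 ± 0.35% of cells) had 3 genes higher and 2 lower, no more higher genes than the 4 that 1 cluster had in the simulated cells with several UMIs per transcript and no other structure. Of these, groL1 at 1.12 lost its call with DESeq2, with its size factors, without the library term and without cluster 11. List calls in cluster 6 held no single gene that passed, and they were lost with an estimated correlation (adjusted p = 0.420 for ribosomal proteins, 0.319 for flagellum and chemotaxis and 0.167 for the TCA cycle). In cluster 7 fatty acid degradation genes were higher, 3 of 5, with an adjusted p of 0.120 with an estimated correlation.

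**Figure D3:**
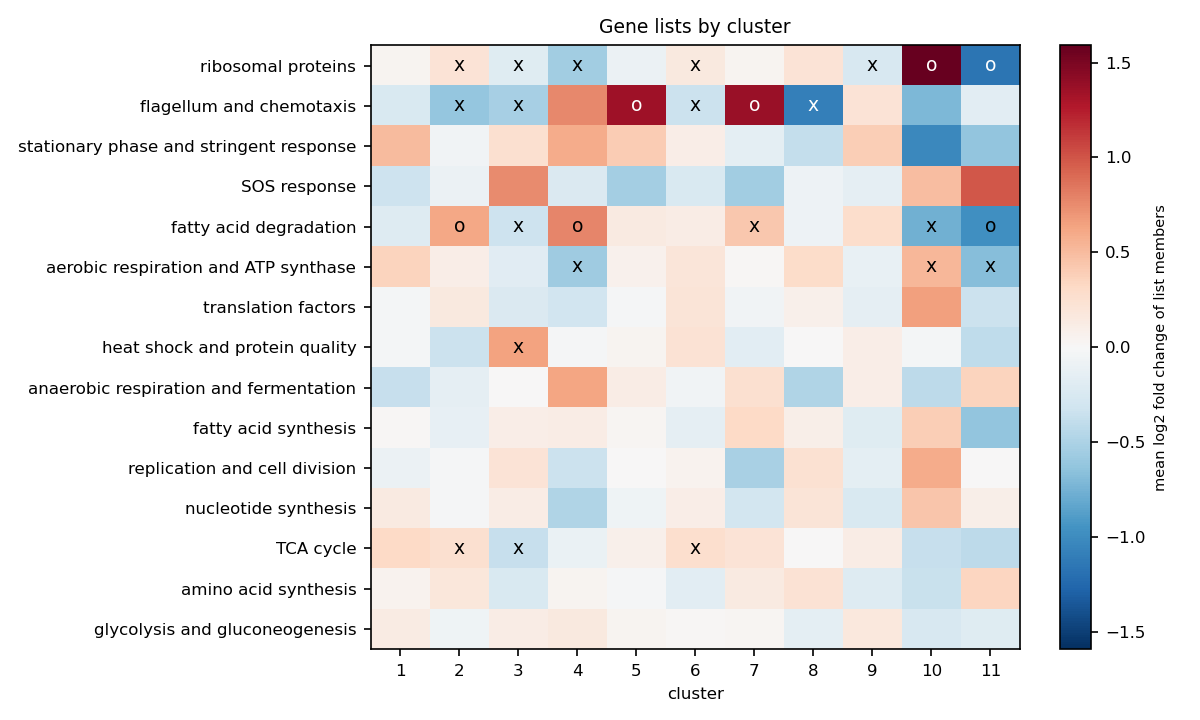
Mean log2 fold change of the tested members of 15 gene lists (vertical axis) in each of the 11 clusters (horizontal axis) against the mean of the others, as colour. A circle marks a camera call that holds with an estimated correlation and a cross a call that is lost with it; 7 of 26 calls hold.

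Over all clusters, 26 of 165 pairs of list and cluster were called, and 7 held with an estimated correlation: fatty acid degradation in clusters 2, 4 and 11, flagellum and chemotaxis in clusters 5 and 7, and ribosomal proteins in clusters 10 and 11. In cluster 11 the call of fatty acid degradation cannot be told apart from the flat profile. On average these genes fell no further than others of like expression, with single genes on both sides. No cluster had a call by camera for translation factors (smallest adjusted p = 0.059), the SOS response (0.140), glycolysis and gluconeogenesis (0.455), anaerobic respiration and fermentation (0.154), fatty acid synthesis (0.687), amino acid synthesis (0.227), nucleotide synthesis (0.114), replication and cell division (0.254) or stationary phase and stringent response (0.241). With fry, 72 pairs of list and cluster were called in place of 26. Of 34 lists, 19 could not be tested, 15 of them because fewer than 5 of their genes carry a symbol in the files; these include type III and type VI secretion, matrix, cyclic di-GMP and pili. With another random split of the UMIs 334 genes were higher and 158 lower, in place of 644 and 297. The fold changes of clusters 2, 6 and 11 had Spearman rho of 0.325, 0.257 and 0.290 across genes with those of their best match in that split, and the other clusters of 0.480 to 0.778; clusters 2, 6 and 10 shared 1 best match.

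To ask which genes varied between cells without use of clusters, the variance of each gene over cells was set against simulated libraries of the same depth. Among the named genes that varied most were the flagellin genes flaA, with a residual variance of 2.84 ± 0.27 where counting noise gives about 1, and flaC, with 2.22 ± 0.33. Metabolic genes among them were malE at 2.52 ± 0.040, fadB at 2.40 ± 0.018, glpK at 2.38 ± 0.15 and ushA, a nucleotidase, at 2.08 ± 0.019. The ribosomal protein genes rpsJ and rpsM stood at 2.11 ± 0.11 and 2.19 ± 0.24, and rplY at 4.14 ± 2.7, with rplN also among them. The rest were folD, mraY, minC, lipB and hisS, between 2.12 and 3.24. Of 2190 genes with enough UMIs, 2022 lay past the highest simulated value in B1 and 2011 in B2. Both libraries shared 1883 of these, where independent lists would share 1857, and 583 of the 1883 had a symbol. With cells of fewer than 108 UMIs left out and the others, 4267 in B1 and 3293 in B2, thinned to 108 UMIs, 1262 of 1285 genes were past it in both libraries. The residual variances of the 2 libraries had a Spearman rho of 0.395 across genes.

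Functions that varied together were sought from the mean correlation over cells of pairs of genes of a list, without pairs within 10 genes of each other. Fatty acid degradation genes had the highest mean r, 0.114 ± 0.0037, above the 95th percentile of random lists of like expression in both libraries. By percentile, 99.99 in B1 and 100 in B2, they did not stand above ribosomal protein, flagellar and heat shock genes, at 100 in both. By mean r, ribosomal protein genes followed at 0.0564 ± 0.0066, flagellum and chemotaxis genes at 0.0211 ± 0.0085 and heat shock and protein quality genes at 0.0140 ± 0.0048. The SOS response (0.0121 ± 0.0037), aerobic respiration and ATP synthase (0.0115 ± 0.0043), translation factors (0.00766 ± 0.0011), anaerobic respiration and fermentation (0.00429 ± 0.00028) and nucleotide synthesis (0.00165 ± 0.00019) were also above the 95th percentile in both. Porins and outer membrane proteins stood at the 98.9th percentile in B1 and the 90.1th in B2. The lists of the TCA cycle, glycolysis and gluconeogenesis, amino acid synthesis, fatty acid synthesis, replication and cell division, stationary phase and stringent response and quorum sensing lay below the 95th percentile in both. At this depth most pairs of genes are seen together in few cells, so the size of r is limited by counting.

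**Figure D4:**
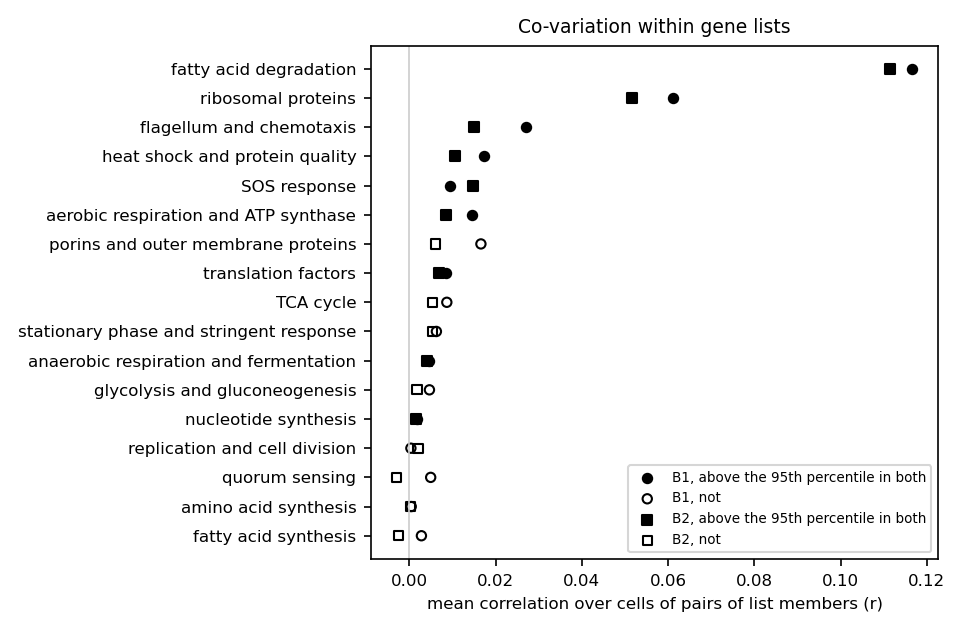
Mean correlation over cells of pairs of genes within each of 17 lists (horizontal axis, r) by list (vertical axis), as circles for B1 and squares for B2; filled symbols lie above the 95th percentile of random lists in both libraries. Fatty acid degradation, at a mean of 0.114, and ribosomal proteins, at 0.0564, stand furthest to the right.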

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

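No result met the rules for outlying samples, for differences between groups or for data left unused, since there is 1 group of 2 libraries; the 3 patterns below were picked for follow-up, and no biological explanation was tested, because the design has no second group. The tests of the overdispersion of genes and of the flagellar genes were chosen only after the result was seen.

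Cluster 11 had a flat profile, with 40.7 ± 2.7% of its UMIs in lower-expressed genes. A flat profile of all cells of some depth is argued against: with cells divided into 10 equal groups by depth, the highest share was 19.6764% on average, near the 17.6% of all cells. Cluster 11 held 102 of 4990 cells in B1 and 125 of 5003 in B2, too few to raise the share of 1 group far. An effect of depth in these cells alone could therefore not have shown. DNA carried over with the RNA, or other reads spread evenly over genes, may contribute and cannot be told apart from a change in the cells: ribosomal protein genes fell further than genes of like expression by a median of -0.420685 (-0.38 in B1, SE 0.069; -0.46 in B2, SE 0.12), between the bounds of 0.25 and 0.5 set beforehand. Gene lengths and the strand of reads, which could decide it, are not in the files. Of the rRNA, cluster 11 held a median of 24 ± 2.8 UMIs per cell and cluster 10, whose profile was not flat, 23.8 ± 2.5.

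Nearly all genes, 1883 of 2190, varied between cells beyond counting noise in both libraries. A few cells with very many UMIs are argued against, since 1879 genes were past the limit without cells of over 1000 UMIs, 1810 of them among the 1883. Several UMIs from 1 transcript, which random priming allows, are consistent with the variance: the excess in the sixth of genes with the fewest UMIs was 56.0723% of that in the sixth with the most, where an excess in proportion to the mean would give 7.30%. A count of variable genes may therefore say little about how many genes differ in expression between cells. Simulated cells had the median variance in every gene and no other structure. Between their clusters 24 of 907 genes differed, against 732 of 1463 in the data. Neither genes of larger variance, such as flaA at 2.84, nor transcripts over several neighbouring genes were simulated. How much of this difference several UMIs per transcript give can therefore not be told.

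Different flagellar genes were higher in different clusters: flaC with ring and hook genes and the motor gene motY in cluster 7 and flaA with motX, motB and chemotaxis genes in cluster 5, while cluster 4 had 8 of 22 genes of the list higher, flgH1 and flgL-1 among them. By plain means of CPM, flgH1 and flgL-1 in cluster 4 lay under 2-fold above the other clusters. Genes of the list were put with flaA or flaC in 1 library by their r and measured in the other. Pairs of the flaA group over 50 genes apart then had a mean r of 0.0491447 (0.0534 in B1 and 0.0448 in B2, above all 10000 random lists of like expression in each). Pieces of 1 transcript counted as several genes are thus argued against for the flaA group. They stay open for the ring and hook genes, whose 10 pairs are all neighbours. The r of motY was measured without such grouping. With flaC and the ring and hook genes its mean was 0.0773 in B1 and 0.0341 in B2, above that of all 152 genes of like expression. As motY had been seen to be high with these genes in cluster 7 of the same cells, this does not decide the question. Reads shared between flagellin genes are argued against for the flaA group, as without these genes the mean r was 0.0463252 (0.0568 in B1 and 0.0358 in B2, also above all random lists). Shallow counts may hide a correlation between the groups and cannot be told apart from a real split: the mean r between the groups was 36.4039% of that within them, 21.6% in B1 and 51.2% in B2, where the mean r within the flaC group was only 0.00381. The r of flaC with flaA was -0.0213 in B1 and -0.0278 in B2 (SE 0.0142 and 0.0141), but 21.4% and 9.53% of pairs of like expression had a lower one, so it does not settle this.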

How the results depend on the processing

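Chosen only after the data were seen were the alternatives without cells of over 1000 UMIs, without cluster 11 and with all UMIs clustered, and the matching of clusters by profile. The number of clusters stayed between 8 and 14 under every alternative, and 8 and 10 when each library was clustered alone. The cells in them changed more. Without cells of over 1000 UMIs 4 of the 11 clusters had a counterpart with a Jaccard index of at least 0.5. With rRNA and tRNA kept 6 had one, with at least 100 and 10 UMIs per cell 7 and 8, and at resolution 1.0 and without centring 9 each. Adjusted Rand indices with the main clusters were 0.285 without cells of over 1000 UMIs, 0.247 with all UMIs clustered, 0.281 in B1 alone and 0.239 in B2 alone. The count of genes differing between clusters lay between 533 and 769 under every alternative but 1. With all UMIs tested it was 1216, with 1153 genes higher and 622 lower. Clusters and tests then shared UMIs, and the sums also held more UMIs, so these 2 changes cannot be told apart. With another random split 334 genes were higher and 158 lower, 16 list calls were made in place of 26, and 0 of the 11 clusters had a counterpart with a Jaccard index of at least 0.5, so per-cluster counts exist for matched clusters only. Matched by profile instead, the clusters of that split had rank correlations of fold changes from 0.257 in cluster 6 to 0.778 in cluster 4, with 0.290 in cluster 11 and 0.325 in cluster 2; clusters 2, 6 and 10 shared 1 best match, so they have no separate counterparts. DESeq2 called 132 genes lower. List calls numbered 7 with an estimated correlation, 72 by fry and 64 without a filter on low counts; fry shared 25 of the 26. With a prior count of 5 the correlation of the libraries was 0.980. The cause of these changes was not tested.

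The counts moved by over 1.5 times from these: genes higher in clusters 1 to 11 numbered 67, 41, 53, 121, 45, 3, 29, 37, 19, 156, 171, and genes lower 6, 10, 15, 61, 2, 2, 9, 8, 1, 98, 117. Without a filter on low counts higher genes numbered 65 in cluster 2, 81 in cluster 3, 5 in cluster 6, 281 in cluster 11 and lower genes numbered 2 in cluster 1, 4 in cluster 2, 7 in cluster 3, 35 in cluster 4, 1 in cluster 5, 1 in cluster 6, 4 in cluster 7, 5 in cluster 8, 268 in cluster 11. With DESeq2 higher genes numbered 28 in cluster 3, 1 in cluster 6 and lower genes numbered 38 in cluster 4, 0 in cluster 6, 1 in cluster 7, 2 in cluster 8, 51 in cluster 10, 28 in cluster 11. With all UMIs tested higher genes numbered 90 in cluster 3, 13 in cluster 6, 47 in cluster 7, 31 in cluster 9, 487 in cluster 11 and lower genes numbered 14 in cluster 1, 17 in cluster 2, 0 in cluster 5, 19 in cluster 6, 13 in cluster 8, 5 in cluster 9, 159 in cluster 10, 365 in cluster 11. With size factors of DESeq2 higher genes numbered 1 in cluster 6 and lower genes numbered 2 in cluster 9, 46 in cluster 11. With each cluster set against all other cells in 4 sums higher genes numbered 6 in cluster 6, 5 in cluster 9 and lower genes numbered 37 in cluster 1, 57 in cluster 2, 28 in cluster 3, 8 in cluster 5, 26 in cluster 6, 15 in cluster 7, 27 in cluster 8. With at least 100 UMIs per cell higher genes numbered 24 in cluster 8 and lower genes numbered 14 in cluster 1, 1 in cluster 5, 3 in cluster 8, 5 in cluster 9, 60 in cluster 10, 191 in cluster 11. With at least 10 UMIs per cell higher genes numbered 23 in cluster 8, 9 in cluster 9 and lower genes numbered 21 in cluster 1, 4 in cluster 7, 3 in cluster 9, 72 in cluster 11. At resolution 1.0 higher genes numbered 7 in cluster 9 and lower genes numbered 13 in cluster 1, 23 in cluster 2, 5 in cluster 7, 0 in cluster 9, 58 in cluster 11. With rRNA and tRNA kept higher genes numbered 294 in cluster 11 and lower genes numbered 1 in cluster 5, 5 in cluster 7, 13 in cluster 8, 3 in cluster 9, 284 in cluster 11. Without centring within libraries lower genes numbered 13 in cluster 1, 3 in cluster 9. Without cells of over 1000 UMIs lower genes numbered 5 in cluster 7, 5 in cluster 8, 2 in cluster 9. Without cluster 11 lower genes numbered 4 in cluster 9. With the 4 sums the share of called genes that were higher moved by over 10 points in clusters 1, 2, 3, 5, 6, 7, 8 and 9; it was 91.8% in cluster 1 and became 63.7%, and 80.4% in cluster 2 and became 43.6%. The median of all genes in cluster 11 moved by 0.246 with size factors of DESeq2 and by 0.117 with all UMIs. The cause was not tested.

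Under the alternatives that kept the clusters, no named gene or called list changed direction. Where cells were clustered anew, named genes were not followed, and lists were followed over all clusters together. The balance of higher and lower genes turned in cluster 2, with 44 higher and 57 lower in the 4 sums, and in cluster 6, with 1 and 2 with size factors of DESeq2, 13 and 19 with all UMIs tested, 6 and 26 in the 4 sums and 2 and 3 without cluster 11. Among values of named genes under alternatives, 1311 kept their side of the threshold or their spread, 130 fell short of it (37 with DESeq2, 24 without a filter on low counts, 23 in the 4 sums, 18 without the library term, 12 with all UMIs, 8 with size factors of DESeq2 and 8 without cluster 11), 34 newly passed and 76 moved by more than the spread in 1 library alone. List calls were kept in 147 comparisons and lost in 32. Over all clusters, heat shock and protein quality genes lost their call at resolution 1.0, with another split and with clusters made without the list. The size of their mean log2 fold change, without its sign, was then 0.58, 0.55 and 0.64 against 0.63. TCA cycle genes lost theirs at resolution 1.0, with another split and with at least 100 and 10 UMIs per cell, at sizes of 0.38, 0.35, 0.90 and 0.39 against 0.37. Aerobic respiration and ATP synthase genes lost theirs with at least 10 UMIs per cell, at a size of 0.60 against 0.67, where the 0.67 was a fall. Called anew were translation factors with clusters made without the list, with rRNA and tRNA kept and without cells of over 1000 UMIs, and anaerobic respiration and fermentation without centring. The count of variable genes was 2022 in B1 alone and 2011 in B2 alone; 10 lists varied together in B1 and 9 in B2, against 9 in both; and the lists together took 20.7% of mRNA UMIs in B1 and 19.5% in B2, 20.1% on average. The caller of doublets, Scrublet, marked 0 of 4990 and 0 of 5003 cells, so leaving out doublets removed no cell, and the clusters were the same 11. With simulated changes in cluster 1, whose sums hold 58957 and 59504 UMIs, 66% of 2-fold and 92% of 4-fold changes were found; changes in the smaller clusters were not simulated.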

Other observations

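The tests in this part were chosen only after the data were seen. Between lists, cells with more ribosomal protein UMIs for their depth had fewer of fatty acid degradation, with a mean r of -0.028 between genes of the lists. They also had fewer of stationary phase and stringent response, with -0.0147. This was not particular to these lists. With flagellum and chemotaxis (-0.0038), quorum sensing (-0.0062) and heat shock and protein quality (-0.0053), no random pair of lists lay lower in either library. As residuals are relative to cell depth, a rise of 1 list can lower others. Ribosomal protein genes varied together with aerobic respiration and ATP synthase genes (0.0206) and with translation factors (0.0183). Genes of the TCA cycle varied together with aerobic respiration and ATP synthase genes (0.0087), while aerobic respiration genes and anaerobic respiration and fermentation genes varied apart (-0.00540). Of 136 pairs of lists, 22 lay below the 2.5th percentile of 1000 random pairs of lists in both libraries and 10 above the matching upper limit.

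The 8 genes malE, malF, malG, malK, malS-1, malS-2, malT and lamB, picked by symbol after malE was seen to vary, had a mean r of 0.0504 ± 0.013 over 28 pairs and of 0.0267 ± 0.0071 over the 21 pairs that lie over 10 genes apart, above all 10000 random lists of like expression in each library. The glycerol phosphate genes glpK, glpT and glpQ, which are neighbours, had a mean r of 0.138 ± 0.051. Genes next to each other in the order of locus tags had a mean r of 0.0291 in B1 and 0.0257 in B2, which was 0.0020 and 0.0016 at 11 to 20 genes apart. The median number of rRNA UMIs per cell ran from 23.8 ± 2.5 in cluster 10 to 59.0 ± 7.1 in cluster 4. The correlations are across cells within each library, and cells are not replicates.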
